A study of Mus musculus with 15 samples.

How the data were processed

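RNA from whole mouse adrenal glands was measured on 15 one-colour Affymetrix arrays, each from a separate animal according to the sample titles. The labels give 4 groups of male C57BL/6J mice: 4 arrays from mice before dexamethasone (control), 3 from the end of 14 days of dexamethasone in the drinking water (withdrawal), 4 from 3 days after withdrawal and 4 from 7 days after withdrawal. RNA was extracted on silica columns, its quality was read on a Bioanalyzer, and biotin-labelled targets were made with a WT Pico kit, per the labels' protocols.

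The deposited values are on a log2 scale and were made with robust multi-array average (RMA) normalization in the oligo package, per the submitters' processing notes. The software versions, the annotation and any filter on probe sets are not given in the sources used here. The table holds 32736 probe sets on 15 arrays, with values from -0.19 to 12.1 and array medians from 1.55 to 1.64. Lower quartiles ran from 0.95 to 1.03 and upper quartiles from 4.65 to 4.77. The mean correlation of an array with the others of its group, over genes, lay between 0.988 and 0.991, and 0 pairs of arrays were identical. Levels around the array medians or under them are taken as the floor of the arrays, where a fall has no room. The floor can hide part of a difference from such a group, and in that sense alone its size is called a lower limit. The standard error and the spread between arrays apply to it as to any other difference. The number of arrays limits the precision of each comparison.

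Of the probe sets, 22399 carried 1 gene symbol, 1607 several and 8730 none in the platform annotation. Only probe sets with 1 symbol were used. Entrez identifiers matched RefSeq genes (GRCm38.p6, used for names alone) for 22261 of them, 138 did not match, and 0 symbols changed. For the 807 genes with more than 1 probe set, the probe set with the highest mean over all arrays was kept, which left 21439 genes.

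Differences were tested with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with lmFit and eBayes without trend or robust options. The 15 arrays entered 1 model with the 4 groups, so that the 6 contrasts share 1 estimate of the spread. P-values were adjusted by Benjamini-Hochberg over all genes within a contrast, with a threshold of 0.05. A difference is given as log2 ± standard error of the model, and a group level as mean ± SD. Gene lists were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the 192 tests of 32 lists in 6 contrasts. Camera compares the members of a list with all other genes. With the correlation estimated from the data, 5 of the 19 list calls held for withdrawal against control, 9 of 17 for day 3 against withdrawal, 5 of 17 for day 7 against withdrawal, 1 of 12 for day 3 against control, 0 of 11 for day 7 against control and 3 of 10 for day 7 against day 3. The rotation test fry, which asks whether the genes of a list move on balance one way and compares them with no other genes, passed 14, 12, 11, 6, 1 and 5 of these calls. For each list that passed, the number of members past the threshold is given over all genes and adjusted over the list alone.

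The groups, the tests, the 33 gene lists and most alternatives were fixed before the data were examined. The lists were adrenal steroid synthesis, the ACTH receptor and ACTH-responsive genes, cholesterol synthesis, cholesterol uptake, storage and transport, zona glomerulosa, zona fasciculata, adrenal capsule, hedgehog signalling, WNT signalling, extracellular matrix, DNA replication, mitosis, glucocorticoid receptor targets, p53 targets, the unfolded protein response, immediate early genes, interferon-stimulated genes and oxidative phosphorylation. Cell type lists covered the medulla (chromaffin cells), macrophage, MHC class II presentation, T cell, B cell, neutrophil, mast cell, endothelium, smooth muscle and pericyte, Schwann and glial cell, adipocyte, red blood cell, kidney, liver and pancreas. The red blood cell list had 3 measured genes and was not tested. Some genes stand in several lists: Scarb1, Mrap, Star and Fdx1, for example, are in both the zona fasciculata and the ACTH list, and Cyp11b2 and Hsd3b6 are in both the zona glomerulosa and the steroid synthesis list.

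Genes are named by a fixed rule. It takes the 8 largest rises and 8 largest falls among genes past the threshold whose groups do not overlap (4 and 4 for day 7 against withdrawal, day 3 against control and day 7 against day 3), without predicted genes, clone names, microRNA, immunoglobulin, olfactory and similar families. It adds up to 4 members of each list that passed, past the threshold in its direction, and 23 genes reported in every comparison, of which 22 were measured here. Akr1b7 was not analysed here.

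The scripts were tested on simulated data made from the means and spread of these arrays, with 200 changed genes per contrast in 3 sizes. At a change of 1 log2 unit the test recovered 87.1% for withdrawal against control, 83.8% for day 3 against withdrawal, 81.4% for day 7 against withdrawal, 84.1% for day 3 against control, 86.3% for day 7 against control and 81.2% for day 7 against day 3. At 0.5 log2 units the shares in the same order were 41.2%, 27.6%, 25%, 40.6%, 25.4% and 34.3%, and at 2 log2 units 98.4%, 98.4%, 100%, 100%, 100% and 96.9%. False calls were 7 of 157, 12 of 156, 5 of 140, 6 of 157, 11 of 154 and 11 of 152. In simulated arrays with no shifted list 0 of the 192 list tests passed. A macrophage list raised by 0.5 log2 units at withdrawal was the 1 list recovered in that contrast. Genes were drawn independently of each other there, so these runs do not show how often camera calls lists whose members vary together.

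The alternatives were a filter on dim probe sets, a further quantile normalization, per-array median centring, eBayes with trend and robust options, array weights, the replicate number as a block, all probe sets with 1 symbol, the probe set with the largest variance, all probe sets of the table, a size threshold of 1 log2 unit, a model of only the 2 groups compared, leaving out each array in turn, camera with an estimated correlation, fry, and controls split between overlapping contrasts. After the data were seen, a fit without recovery day 3 replicates 1 and 2 and a fit with the liver and neutrophil list means of each array as covariates were added, and later the withdrawal arrays were split between the contrasts that share them. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.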

Results

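Gene expression was measured in the adrenal glands of male mice before dexamethasone, at the end of a 14 day treatment, and 3 and 7 days after it was withdrawn. Dexamethasone is a synthetic glucocorticoid. It lowers pituitary ACTH, the hormone that drives the zona fasciculata, the cortical layer that makes corticosterone in mice. The series set out to follow how the gland regenerates once the drug is removed. There were 4 control arrays, 3 withdrawal arrays, 4 arrays at recovery day 3 and 4 at recovery day 7. Each is titled as a biological replicate, and each comparison below uses these numbers. The labels give an age of 6 weeks for all arrays. Controls were taken before treatment, so that treatment, recovery and the days that had passed go together in every comparison with control. Of 21439 genes, the median level over all arrays was 2.45 on the log2 scale.

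At withdrawal, genes of the zona fasciculata were lower than in control and genes of macrophages were higher. Cyp21a1, the steroid 21-hydroxylase (probe set 17343962), fell from 9.56 ± 0.07 (SD, n = 4) to 8.30 ± 0.19 (n = 3), 2.40-fold lower (limma, adjusted p = 7.6e-06). The ACTH receptor accessory protein Mrap (probe set 17326987) fell from 9.13 ± 0.14 to 7.35 ± 0.10, or 3.45-fold, and Scarb1, the receptor that takes up lipoprotein cholesterol, fell 3.34-fold. Gpnmb, a glycoprotein of lipid-laden macrophages (probe set 17458439), rose from 1.57 ± 0.42, at the floor of the arrays, to 9.20 ± 0.54, so that the size of its rise is a lower limit. The matrix metalloproteinase Mmp12 (probe set 17514495) rose 13.8-fold, from 3.52 to 7.31.

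Of the 9 measured zona fasciculata genes, 7 fell, 0 rose and 2 did not pass, and the same 7 fell adjusted over the list alone; the median member differed by -0.73 log2 (camera, adjusted p = 6.84e-16). The examples are Mrap with -1.79 ± 0.13, Scarb1 with -1.74 ± 0.17, the transporter Abcb1b with -1.59 ± 0.17 and Cyp21a1 with -1.26 ± 0.09. In the steroid synthesis list of 10 genes, 6 fell and 2 rose (7 and 2 adjusted over the list alone), with a median of -0.41 and an adjusted p of 9.59e-06. Cyp11b1, which makes corticosterone, differed by -0.73 ± 0.11, the mitochondrial carrier protein Tspo by -0.72 ± 0.13 and the electron donor Fdx1 by -0.71 ± 0.12. Cyp11a1, the side-chain cleavage enzyme, fell by 0.46 ± 0.08 and Star, which brings cholesterol into mitochondria, fell by 0.36 ± 0.08. A further probe set of Cyp11a1 went the same way without passing, and with the probe set of largest variance the adjusted p was 0.532. The 2 genes that rose are glomerulosa enzymes, Cyp11b2 and Hsd3b6. Hsd3b1 differed by -0.24 (adjusted p = 0.353), the regulator Nr5a1 by -0.31 (0.165) and the ACTH receptor Mc2r by -0.13 (0.581). Among 10 ACTH-responsive genes 5 fell and 0 rose (5 and 2 adjusted over the list alone), with a median of -0.24 and an adjusted p of 0.004; with an estimated correlation the adjusted p was 0.164. The phosphodiesterase Pde8b fell by 1.08 ± 0.26. Of 19 cholesterol synthesis genes 6 fell, 0 rose and 13 did not pass, against 10 falling adjusted over the list alone (median -0.41, adjusted p = 7.57e-09, and adjusted p = 0.154 with an estimated correlation). Dhcr7, which catalyses the last step to cholesterol, differed by -2.05 ± 0.16, Fdps by -1.72 ± 0.21, Tm7sf2 by -1.22 ± 0.25 and Lss by -1.03 ± 0.21. Oxidative phosphorylation genes were lower as a group by a median of -0.16 (adjusted p = 1.96e-05), with 1 of 23 members falling, Uqcrfs1 at -0.48 ± 0.08, and 2 adjusted over the list alone.

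Genes of the outer cortex went the other way. Among 12 zona glomerulosa genes 5 rose, 0 fell and 7 did not pass (6 rose and 1 fell adjusted over the list alone), with a median of 0.55 and an adjusted p of 7.73e-05. Hsd3b6 rose by 1.66 ± 0.32, the WNT target Axin2 by 1.29 ± 0.16, the aldosterone synthase Cyp11b2 by 0.90 ± 0.16 and the calcium sensor Vsnl1 by 0.72 ± 0.18. Nr0b1, a repressor of steroidogenic genes, rose by 1.02 ± 0.17. The capsule list was higher by a median of 0.39 (adjusted p = 0.00132; adjusted p = 0.108 with an estimated correlation), with Gli2 at 0.57 ± 0.14 the 1 of 12 members that rose by either adjustment. Gli2 lies near the floor, at 1.30 in control and 1.87 at withdrawal, so that the floor can hide part of its change. Of 21 WNT signalling genes Axin2, Lgr5 (0.84 ± 0.15) and Wnt4 (0.63 ± 0.15) rose by either adjustment, with a median of 0.26 and an adjusted p of 0.0143. That call was lost with an estimated correlation (adjusted p = 0.154) and with a filter on dim probe sets (0.0781). Hedgehog signalling had 1 rising member of 13, again Gli2, a median of 0.18 and an adjusted p of 0.0487, which became 0.461 with an estimated correlation. Single genes of these routes did not pass: Ptch1 at 0.48 (adjusted p = 0.22), Rspo3 at 0.44 (0.343), Shh at 0.19 (0.536) and Gli1 at 0.06 (0.944). The group means of Gli1 lie at the floor, at 1.395 in control, 1.452 at withdrawal, 1.129 at day 3 and 1.252 at day 7. Here and in the comparisons below Gli1 was thus not measured above the floor, and a fall of it could not be seen.

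Of 22 macrophage genes 16 rose, 0 fell and 6 did not pass (18 and 1 adjusted over the list alone), with a median of 0.91 and an adjusted p of 2.78e-21. Gpnmb was 198-fold higher by its group means (7.63 ± 0.82). The lipid receptor Trem2 rose by 2.96 ± 0.34, the lysosomal protein Cd68 by 2.29 ± 0.30 and the pore-forming Mpeg1 by 1.77 ± 0.21. Further genes among the largest rises were the proton pump subunit Atp6v0d2 (5.77 ± 0.81), Clec4d (3.57 ± 0.61), Il7r (3.33 ± 0.63), Cd84 (3.03 ± 0.38) and Spink4 (2.86 ± 0.47). Control levels of Gpnmb, Atp6v0d2 (1.52), Clec4d (1.68), Il7r (1.40) and Spink4 (1.15) lie at the floor, so that these sizes are lower limits and their ranks are not exact. Spink4 differed by 2.10 without withdrawal replicate 1 and by 3.58 without withdrawal replicate 3, and Il7r by 2.73 without withdrawal replicate 2. Among the largest falls were the kinase Mapk13 (-2.96 ± 0.22, probe set 17335383), Vnn3 (-2.46 ± 0.49), Rhcg (-2.39 ± 0.48), the tachykinin receptor Tacr2 (-2.27 ± 0.23), the gap junction protein Gja1 (adjusted p = 0.000359), Tmem144 (-1.94 ± 0.23) and Cryba4 (-1.93 ± 0.31). The withdrawal levels of Vnn3 (1.78) and Rhcg (2.00) are near the floor. Control replicate 2 lay below the other controls for Vnn3, Tacr2, Cryba4 and Mrap, and control replicate 1 for Abcb1b and Atf3.

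**Figure D1:**
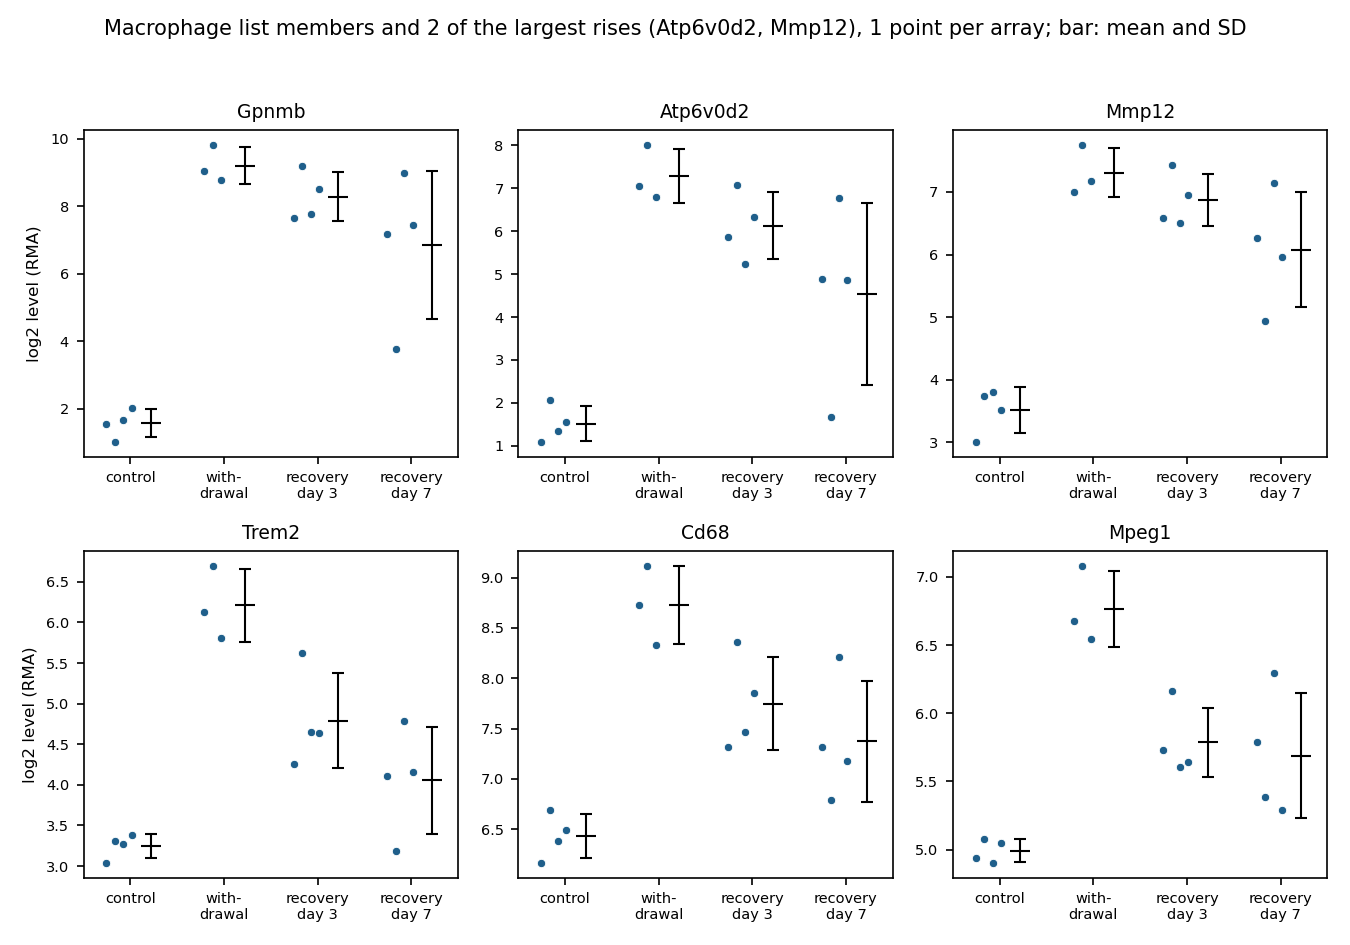
Log2 level (y axis, not from 0) of 4 members of the macrophage list (Gpnmb, Trem2, Cd68, Mpeg1) and of Atp6v0d2 and Mmp12 by group, 1 point per array, with the bar at the mean and SD as error. Gpnmb has means of 1.57 in control, 9.20 at withdrawal, 8.28 at day 3 and 6.85 at day 7, where its SD of 2.19 is the widest of its 4 groups.

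Medulla genes were higher at withdrawal by a median of 0.50 (adjusted p = 4.12e-08; adjusted p = 0.252 with an estimated correlation). Among the 20, 3 rose (10 adjusted over the list alone): the synaptic protein Syt1 by 0.89 ± 0.22, Cyb561 by 0.67 ± 0.15 and Ddc, which makes dopamine, by 0.64 ± 0.13, while Th differed by 0.26 (adjusted p = 0.709). Schwann and glial genes had a median of 0.42 and 0 of 9 members past the threshold (5 adjusted over the list alone; adjusted p = 0.00173, or adjusted p = 0.062 with an estimated correlation). T cell genes, near the floor in control, had a median of 0.28, with Il7r and Cd4 (0.72 ± 0.17, from 1.22, at the floor) rising of 12 by either adjustment (adjusted p = 0.0321; adjusted p = 0.271 with an estimated correlation). Endothelial genes were lower by a median of -0.34 (adjusted p = 3.06e-06; adjusted p = 0.0645 with an estimated correlation), with 2 of 16 falling (4 adjusted over the list alone), the apelin receptor Aplnr by 1.35 ± 0.27 and the VEGF receptor Kdr by 0.77 ± 0.17. Immediate early genes had a median of 0.50 and 3 rising of 16 (4 adjusted over the list alone), Atf3 at 1.72 ± 0.30, Klf4 at 1.07 ± 0.25 and Klf6 at 0.56 ± 0.13, whose groups overlap (adjusted p = 8.79e-05; adjusted p = 0.258 with an estimated correlation).

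Smaller list shifts had few or no members past the threshold. Glucocorticoid receptor targets had a median of 0.24 with 0 of 20 members passing by either adjustment (adjusted p = 0.0213; adjusted p = 0.169 with an estimated correlation), and Fkbp5 differed by 0.21 (0.62). For p53 targets the median was 0.22 with 0 of 13 (adjusted p = 0.0298; adjusted p = 0.112 with an estimated correlation). Mitosis genes had a median of -0.22 with 0 of 28 passing by either adjustment (adjusted p = 0.014; adjusted p = 0.534 with an estimated correlation); Mki67 differed by -0.38 (0.405) and Top2a by -0.32 (0.515). For interferon-stimulated genes the median was -0.31, with Gbp3 at -0.54 ± 0.14 the 1 of 15 that fell (adjusted over the list alone, 3 fell and 1 rose; adjusted p = 0.0156, or adjusted p = 0.423 with an estimated correlation). The lists that did not pass were cholesterol uptake (adjusted p = 0.478, with 3 members rising and 1 falling), extracellular matrix (0.206), DNA replication (0.689), unfolded protein response (0.442), MHC class II presentation (0.713), B cell (0.993), neutrophil (0.725), mast cell (0.0752), smooth muscle and pericyte (0.673), adipocyte (0.875), kidney (0.0642), liver (0.492) and pancreas (0.689). Akr1c18 and Pik3c2g stayed at the floor, with adjusted p of 0.746 and 0.859.

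Limma called 534 genes higher and 387 lower at withdrawal than in control, of which 151 and 78 differed at least 2-fold. Over all 21439 genes the groups did not overlap for 3234, where chance gives 5.71% with groups of 3 and 4. Per-array median centring moved the median of all genes by -0.11 log2 and the split to 341 higher and 853 lower, and a further quantile normalization gave 421 and 462; the medians of the lists that passed lie further from 0 than that shift. With the centring Vsnl1, Gli2, Wnt4, Klf6 and Syt1 no longer passed (adjusted p from 0.0543 to 0.0724). Without withdrawal replicate 2 the counts were 243 and 216. Without withdrawal replicate 1 there were 338 higher, and without control replicate 4 there were 354 higher. Of the 50 named differences that passed, 35 held in each of the 7 fits without 1 array. The highest adjusted p without withdrawal replicate 2 was 0.103 for Pde8b, 0.151 for Vsnl1, 0.152 for Gbp3, 0.13 for Wnt4, 0.0909 for Cyb561, 0.144 for Syt1, 0.0503 for Il7r and 0.0688 for Lss. It was 0.14 for Gli2, 0.0893 for Klf4 and 0.0605 for Tm7sf2 without withdrawal replicate 3. Without withdrawal replicate 1 it was 0.0975 for Cd4, 0.125 for Klf6, 0.0686 for Kdr and 0.0707 for Star. Pde8b passed in only 1 of the 7 fits, and Cd4, Gbp3, Klf6, Syt1, Vsnl1 and Wnt4 in 2 each. The list calls lost in such a fit, each with the array of its highest adjusted p, were mitosis (0.249) and interferon-stimulated genes (0.0516) and glucocorticoid receptor targets (0.0563) without control replicate 1, hedgehog signalling (0.13) and T cell (0.115) without control replicate 2, and p53 targets (0.0656) without withdrawal replicate 3. Of the 7 fits, hedgehog signalling was lost in 5, and mitosis, T cell and p53 targets in 2 each. With the filter on dim probe sets, hedgehog signalling (0.391), glucocorticoid receptor targets (0.107) and p53 targets (0.192) also did not pass, and with a further quantile normalization hedgehog signalling had 0.148.

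**Figure D2:**
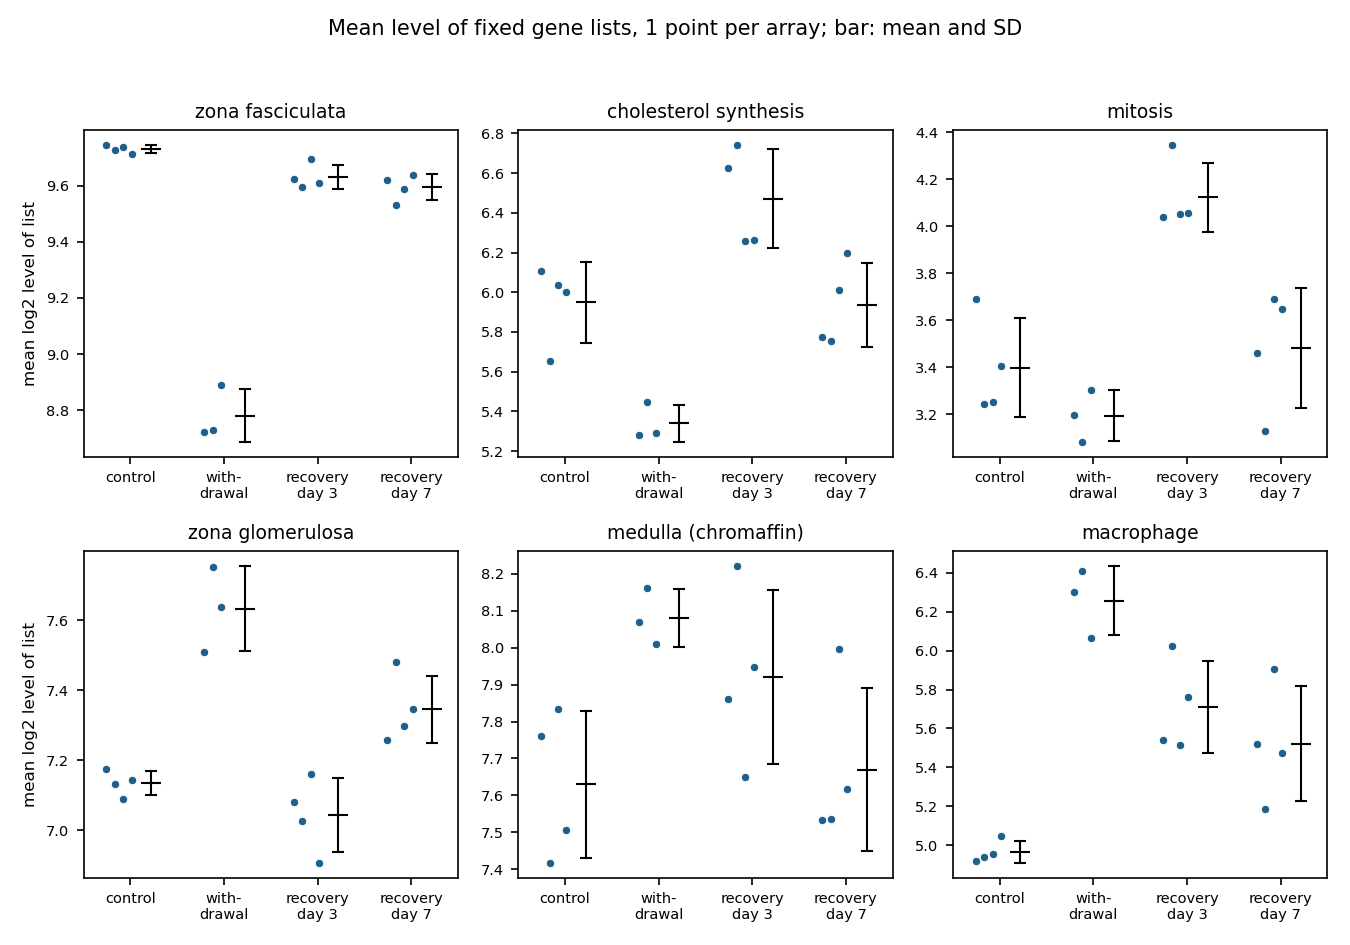
Mean log2 level (y axis, not from 0) of the members of 6 gene lists by group, 1 point per array, with the bar at the mean and SD as error. The zona fasciculata mean was 9.73 ± 0.01 in control, 8.78 ± 0.09 at withdrawal, 9.63 ± 0.04 at day 3 and 9.59 ± 0.05 at day 7, and the macrophage mean was 4.96, 6.26, 5.71 and 5.52.

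By day 3 after withdrawal, steroid and cholesterol synthesis genes and cell division genes were higher than at withdrawal. Cyp21a1 rose to 9.44 ± 0.05 (SD, n = 4), a difference of 1.15 ± 0.09 log2 and 2.21-fold (limma, adjusted p = 3.2e-05). The proliferation marker Mki67 rose 2.39-fold, from 4.29 to 5.55, and Tm7sf2, a sterol reductase, rose 4.92-fold. The macrophage gene Trem2 fell by 1.42 ± 0.34, while Gpnmb stood at 8.28 ± 0.72.

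All 9 zona fasciculata genes had higher means than at withdrawal, 6 passed (8 adjusted over the list alone), and the median was 0.77 (adjusted p = 1.99e-17). Scarb1 rose by 1.65 ± 0.17, Mrap by 1.35 ± 0.13 and Abcb1b by 1.32 ± 0.17. In the steroid synthesis list 5 of 10 rose and 1 fell (6 and 2 adjusted over the list alone; median 0.29, adjusted p = 4.1e-06), with Tspo at 0.80 ± 0.13, Cyp11b1 at 0.77 ± 0.11, Fdx1 at 0.70 ± 0.12 and Cyp11a1 at 0.34 ± 0.08. The gene that fell is Hsd3b6, by 1.81 ± 0.32. Star differed by 0.24 (adjusted p = 0.149), Nr5a1 by 0.23 (0.382), Hsd3b1 by 0.20 (0.514) and Mc2r by 0.26 (0.249). Of the 10 ACTH-responsive genes 3 rose (5 adjusted over the list alone; median 0.25, adjusted p = 0.000678, and adjusted p = 0.112 with an estimated correlation). Cholesterol synthesis genes had a median of 0.97: 14 of 19 rose, 0 fell and 5 did not pass, against 18 rising adjusted over the list alone (adjusted p = 9.05e-28). Beside Tm7sf2 at 2.30 ± 0.25 the examples are Sqle, which makes squalene epoxide, at 1.95 ± 0.34, Cyp51 at 1.95 ± 0.35 and Fdps at 1.93 ± 0.21. Oxidative phosphorylation had 4 rising members of 23 (8 adjusted over the list alone; median 0.22, adjusted p = 2.76e-11), with Cox5b at 0.60 ± 0.12, Cyc1 at 0.46 ± 0.10, Uqcrfs1 at 0.40 ± 0.08 and Ndufs1 at 0.38 ± 0.09.

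Mitosis genes had a median of 0.98, with 14 of 28 rising, 0 falling and 14 not passing (27 rising adjusted over the list alone; adjusted p = 9.05e-28). Top2a rose by 1.32 ± 0.22, Birc5 by 1.26 ± 0.17, Mki67 by 1.25 ± 0.22 and Aurkb by 1.21 ± 0.26. The withdrawal levels of Birc5 (1.88) and Aurkb (1.90) are near the floor, so that these sizes are lower limits. The mitosis mean of day 3 replicate 2 lay above those of the other day 3 arrays. DNA replication had 3 rising members of 27 (7 adjusted over the list alone), Uhrf1 by 1.46 ± 0.32, Dtl by 1.16 ± 0.21 (from a level at the floor) and Cdc45 by 0.92 ± 0.21, with a median of 0.26 and an adjusted p of 5.47e-07, or adjusted p = 0.0982 with an estimated correlation. Endothelial genes were higher by a median of 0.34 (adjusted p = 1.08e-08), 3 of 16 rising (8 adjusted over the list alone), Aplnr by 1.86 ± 0.27, Erg by 1.08 ± 0.20 and Pecam1 by 0.39 ± 0.08.

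Zona glomerulosa genes were lower by a median of -0.57 (adjusted p = 3.48e-08), with 4 of 12 falling and 0 rising (9 falling adjusted over the list alone). Beside Hsd3b6, Vsnl1 differed by -1.02 ± 0.18, the angiotensin receptor Agtr1b by -0.86 ± 0.18 and Axin2 by -0.82 ± 0.16; Cyp11b2 differed by -0.55 (adjusted p = 0.108), Wnt4 by -0.59 (0.0592) and Shh by -0.35 (0.245). The capsule list had a median of -0.36 (adjusted p = 2.79e-05) with 2 of 12 falling (6 adjusted over the list alone), Tcf21 at -0.77 ± 0.18 and Gli2 at -0.61 ± 0.14. Ptch1 differed by -0.74 (0.0706), Rspo3 by -0.56 (0.261), Gli1 by -0.32 (0.632) and Nr0b1 by -0.47 (0.212). WNT signalling had a median of -0.32 and 1 of 21 falling, Axin2 (2 adjusted over the list alone; adjusted p = 0.00017). Hedgehog signalling had a median of -0.32 and 1 of 13 falling, Gli2 (2 adjusted over the list alone; adjusted p = 0.0213, and adjusted p = 0.384 with an estimated correlation). Extracellular matrix genes had a median of -0.28 and 1 of 23 falling by either adjustment, Postn at -0.82 ± 0.17 (adjusted p = 0.0136; adjusted p = 0.407 with an estimated correlation). Of 22 macrophage genes 8 fell and 0 rose (13 adjusted over the list alone), with a median of -0.62 (adjusted p = 1.23e-10; adjusted p = 0.112 with an estimated correlation). Mpeg1 fell by 0.98 ± 0.21, Laptm5 by 0.86 ± 0.19 and the complement gene C1qb by 0.80 ± 0.16. Medulla genes had a median of -0.20 with 0 of 20 passing (adjusted p = 0.0284; adjusted p = 0.668 with an estimated correlation) and Th at -0.12 (0.915). Glucocorticoid receptor targets had a median of -0.19 with 0 of 20 (adjusted p = 0.0438; adjusted p = 0.231 with an estimated correlation) and Fkbp5 at -0.22 (0.646).

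The largest rises were Mapk13 (2.83 ± 0.22), Cryba4 (2.67 ± 0.31), Tm7sf2, the defensin Defb19 (2.06 ± 0.25), the linker histone H1f5 (1.96 ± 0.29), Sqle, Cyp51 and Fdps. The largest falls were Spink4 (-2.81 ± 0.47), the potassium channel Kcnk5 (-2.17 ± 0.35), Cd5l (-2.08 ± 0.42), Aldh1a7 (-1.99 ± 0.49), the GABA receptor subunit Gabrg3 (-1.96 ± 0.32), Hsd3b6, the macrophage transcription factor Spic (-1.79 ± 0.25) and Ggt5 (-1.77 ± 0.20). At day 3 Spink4 (1.21), Cd5l (1.08) and Gli2 (1.26) lie at the floor and Spic (2.09) near it, so that these falls are lower limits in size and their ranks are not exact. Spink4 differed by -2.04 without withdrawal replicate 1 and by -3.53 without withdrawal replicate 3, and Cd5l by -1.48 without withdrawal replicate 2. Day 3 replicate 1 was low for H1f5. Control arrays, which enter the estimate of the spread, stood apart for Sqle, Tcf21 and Aldh1a7 (replicate 2), Gabrg3 (replicate 3) and Erg (replicate 4). Genes of another tissue moved in this comparison: liver genes had a median of 1.15 with 0 of 11 past the threshold (adjusted p = 0.0016; adjusted p = 0.476 with an estimated correlation). Their mean was 5.44 in day 3 replicate 1 against 2.21 to 3.77 in the other day 3 arrays and 2.22 to 2.43 at withdrawal. Without that array the adjusted p was 0.154. Neutrophil genes averaged 3.09 in day 3 replicate 2 and 1.44 to 1.69 in the other day 3 arrays.

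**Figure D3:**
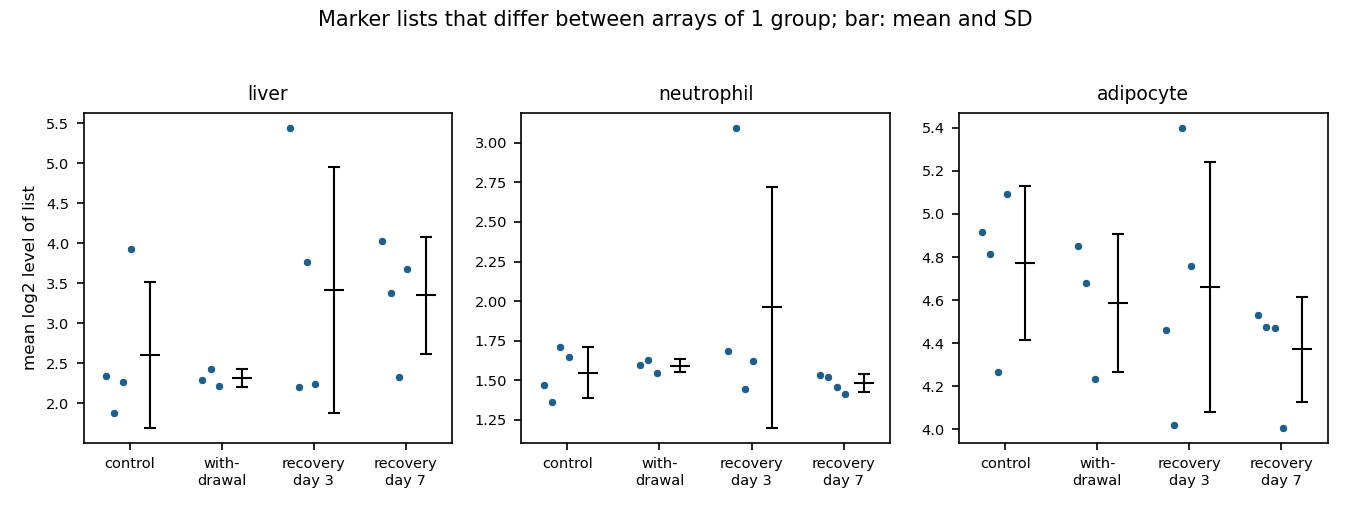
Mean log2 level (y axis, not from 0) of the liver, neutrophil and adipocyte lists by group, 1 point per array, with the bar at the mean and SD as error. The highest arrays were day 3 replicate 1 at 5.44 for liver, day 3 replicate 2 at 3.09 for neutrophil and day 3 replicate 3 at 5.40 for adipocyte.

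Limma called 293 genes higher and 190 lower at day 3 than at withdrawal, 78 and 43 of them at least 2-fold, and over all 21439 genes the groups did not overlap for 2599 (5.71% by chance). Without withdrawal replicate 2 the counts were 130 and 79. Without withdrawal replicate 3 there were 155 higher, and without withdrawal replicate 1 there were 125 lower. Without day 3 replicate 4 there were 194 and 121, and without day 3 replicate 1 there were 113 lower. Of the 48 named differences that passed, 27 held in each fit without 1 array. The highest adjusted p without withdrawal replicate 2 was 0.178 for Aldh1a7, 0.119 for Agtr1b, 0.103 for Aurkb, 0.0805 for C1qb, 0.0795 for Cd5l, 0.0704 for Erg, 0.132 for Laptm5, 0.121 for Mpeg1, 0.155 for Tcf21, 0.182 for Trem2 and 0.0701 for Uqcrfs1. It was 0.15 for Cdc45, 0.0915 for Cyc1, 0.135 for Gli2, 0.0813 for Postn and 0.094 for Uhrf1 without withdrawal replicate 3. Without withdrawal replicate 1 it was 0.0743 for Axin2, 0.061 for Cox5b, 0.124 for Cyp11a1, 0.139 for Ndufs1 and 0.0853 for Pecam1. Cyp11a1, Ndufs1, Pecam1, Tcf21, Trem2, Cdc45 and Uhrf1 passed in only 1 of the 7 fits each. The list calls lost, each with the array of its highest adjusted p, were extracellular matrix (0.1) without withdrawal replicate 1, glucocorticoid receptor targets (0.178) and hedgehog signalling (0.111) without day 3 replicate 1, and medulla (0.311) without day 3 replicate 3. Of the 7 fits, extracellular matrix, glucocorticoid receptor targets and medulla were lost in 3 each and hedgehog signalling in 2. With the filter on dim probe sets the adjusted p was 0.173 for hedgehog signalling, 0.0664 for extracellular matrix, 0.0885 for glucocorticoid receptor targets and 0.0911 for medulla. With a further quantile normalization it was 0.0555 for Gli2, 0.0526 for Ndufs1 and 0.102 for Cyp11a1. Without both day 3 replicates 1 and 2, chosen after the data were seen, 145 genes were higher and 60 lower, and with the liver and neutrophil means as covariates 102 and 35.

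**Figure D4:**
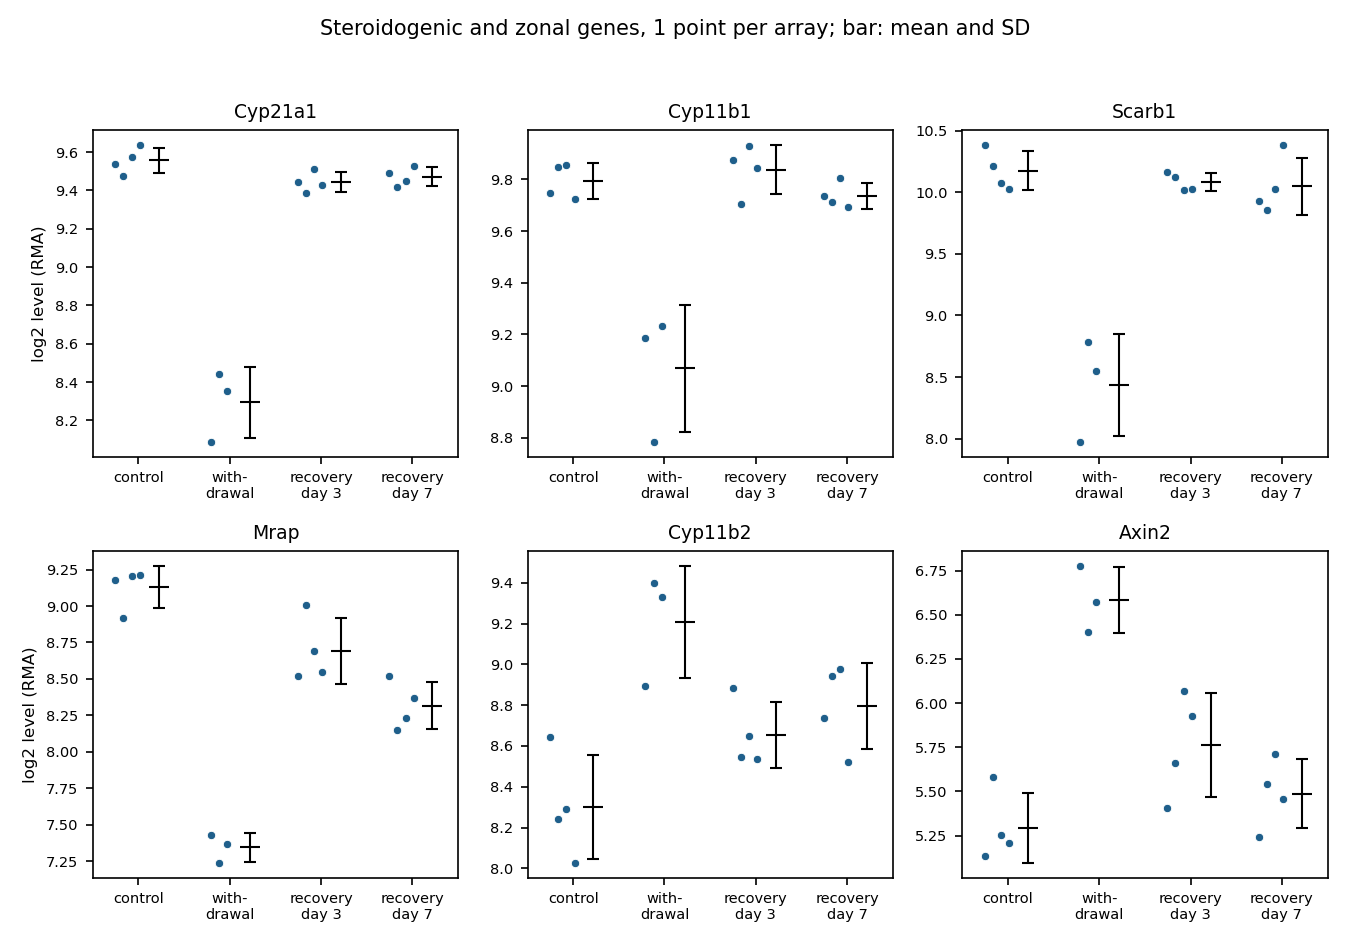
Log2 level (y axis, not from 0) of 6 steroid and zonation genes by group, 1 point per array, with the bar at the mean and SD as error. Mrap has means of 9.13 in control, 7.35 at withdrawal, 8.69 at day 3 and 8.32 at day 7, and Cyp11b2 of 8.30, 9.21, 8.66 and 8.80.

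The comparison of day 7 with withdrawal covers the whole recovery interval. Zona fasciculata genes were higher and macrophage genes lower than at withdrawal (adjusted p = 0.0614 with an estimated correlation for the latter). Cyp21a1 stood at 9.47 ± 0.05 (SD, n = 4), 2.26-fold above withdrawal (limma, adjusted p = 3.04e-05), and Scarb1 was 3.07-fold higher. Trem2 fell by 2.15 ± 0.34, from 6.21 to 4.06.

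Of 9 zona fasciculata genes 7 rose by either adjustment and 0 fell (median 0.67, adjusted p = 1.57e-16), among them Scarb1 at 1.62 ± 0.17, Abcb1b at 1.54 ± 0.17 and Mrap at 0.97 ± 0.13. In the steroid synthesis list 6 of 10 rose and 0 fell (7 and 2 adjusted over the list alone; median 0.40, adjusted p = 4.83e-08), with Tspo at 0.68 ± 0.13, Cyp11b1 at 0.67 ± 0.11, Fdx1 at 0.66 ± 0.12, Cyp11a1 at 0.39 ± 0.08 and Star at 0.36 ± 0.08. Nr5a1 differed by 0.41 (adjusted p = 0.083), Hsd3b1 by 0.18 (0.606) and Mc2r by 0.15 (0.598). ACTH-responsive genes had 4 of 10 rising by either adjustment (median 0.40, adjusted p = 4.33e-05; adjusted p = 0.0645 with an estimated correlation). Cholesterol synthesis had 5 of 19 rising (8 adjusted over the list alone; median 0.47, adjusted p = 6.93e-10, and adjusted p = 0.133 with an estimated correlation), Dhcr7 by 1.82 ± 0.16, Fdps by 1.49 ± 0.21, Tm7sf2 by 1.38 ± 0.25 and Lss by 0.94 ± 0.21. Oxidative phosphorylation had a median of 0.19 and 1 of 23 rising, Uqcrfs1 at 0.45 ± 0.08 (7 adjusted over the list alone; adjusted p = 6.68e-08). Endothelial genes had a median of 0.34 and 2 of 16 rising, Aplnr at 1.67 ± 0.27 and Kdr at 0.75 ± 0.17 (10 adjusted over the list alone; adjusted p = 2.46e-07). Mitosis genes were higher by a median of 0.33 with 0 of 28 passing by either adjustment (adjusted p = 0.000128; adjusted p = 0.366 with an estimated correlation), Mki67 at 0.45 (0.394) and Top2a at 0.46 (0.388). Interferon-stimulated genes had a median of 0.31 and 1 of 15 rising, Ifit2 at 0.61 ± 0.13 (6 rising and 2 falling adjusted over the list alone; adjusted p = 0.0125, and adjusted p = 0.407 with an estimated correlation).

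Macrophage genes had a median of -0.69, with 10 of 22 falling and 0 rising (16 adjusted over the list alone, adjusted p = 2.42e-15 by camera). As given above, this call did not pass with an estimated correlation. Cd68 fell by 1.35 ± 0.30, Mpeg1 by 1.08 ± 0.21 and Laptm5 by 0.92 ± 0.19. Medulla genes had a median of -0.43 and 1 of 20 falling, Ddc at -0.67 ± 0.13 (8 adjusted over the list alone; adjusted p = 1.12e-08, and adjusted p = 0.231 with an estimated correlation), with Th at -0.27 (0.76). Zona glomerulosa genes had a median of -0.28 and 1 of 12 falling by either adjustment, Axin2 at -1.10 ± 0.16 (adjusted p = 0.0058; adjusted p = 0.127 with an estimated correlation), with Cyp11b2 at -0.41 (0.261), Wnt4 at -0.38 (0.26) and Shh at -0.08 (0.878). WNT signalling had a median of -0.18 and 2 of 21 falling by either adjustment, Axin2 and Lgr5 at -0.64 ± 0.15 (adjusted p = 0.0144; adjusted p = 0.154 with an estimated correlation). Nr0b1 fell by 0.82 ± 0.17. Lists with 0 members past the threshold were capsule (median -0.37, adjusted p = 4.66e-05, 3 of 12 falling adjusted over the list alone) and hedgehog signalling (-0.25, 0.0284; adjusted p = 0.407 with an estimated correlation). They also were extracellular matrix (-0.30, 0.00249, 7 of 23 falling adjusted over the list alone; adjusted p = 0.329 with an estimated correlation) and Schwann and glial cell (-0.39, 0.00324; adjusted p = 0.0749 with an estimated correlation). Gli1 differed by -0.20 (0.813), Ptch1 by -0.31 (0.558), Rspo3 by -0.41 (0.471) and Fkbp5 by -0.22 (0.663). Liver genes had a median of 0.96 with 0 of 11 passing (adjusted p = 0.0107; adjusted p = 0.575 with an estimated correlation), with means of 4.03, 3.37, 2.33 and 3.67 in the 4 day 7 arrays.

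The largest rises were Mapk13 (2.76 ± 0.22), Cryba4 (2.60 ± 0.31), Defb19 (2.20 ± 0.25) and Tacr2 (1.98 ± 0.23), and the largest falls Spink4 (-2.77 ± 0.47, to 1.24, at the floor), Trem2, Wfdc17 (-1.72 ± 0.37) and Kcnk5 (-1.69 ± 0.35). Spink4 differed by -2.01 without withdrawal replicate 1 and by -3.50 without withdrawal replicate 3. Day 7 replicate 3 lay above the other day 7 arrays for Lgr5, Ddc and Wfdc17, and replicate 2 lay below them for Top2a. Limma called 210 genes higher and 194 lower, 53 and 46 of them at least 2-fold, and over all 21439 genes the groups did not overlap for 2647 (5.71% by chance). Per-array median centring gave 391 higher and 134 lower, with Lgr5 at an adjusted p of 0.0598. Without withdrawal replicate 2 the counts were 125 and 75, without withdrawal replicate 1 there were 119 lower, and without day 7 replicates 1, 2 and 4 in turn there were 90, 91 and 86 lower. Of the 32 named differences that passed, 20 held in each fit without 1 array. The highest adjusted p without withdrawal replicate 2 was 0.102 for Wfdc17, 0.099 for Kcnk5, 0.153 for Lss, 0.139 for Lgr5, 0.149 for Cd68, 0.0868 for Mpeg1, 0.108 for Laptm5, 0.107 for Ifit2 and 0.0909 for Nr0b1. Without withdrawal replicate 1 it was 0.107 for Star, 0.118 for Kdr and 0.0788 for Cyp11a1. Star passed in 0 of the 7 fits, Lgr5 in 1, Kdr, Cd68, Laptm5 and Wfdc17 in 2 each and Cyp11a1 in 4. The list calls lost, each with the array of its highest adjusted p, were hedgehog signalling (0.101) and WNT signalling (0.0555) without day 7 replicate 3, interferon-stimulated genes (0.182) without day 7 replicate 4 and liver (0.068) without day 7 replicate 1. Hedgehog signalling was lost in 4 of the 7 fits. Hedgehog signalling had an adjusted p of 0.253 with the filter on dim probe sets and 0.0546 with a further quantile normalization, where Star had 0.0589.

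Compared with control, day 3 glands had higher levels of macrophage, cholesterol synthesis and mitosis genes as groups, with 1 of 22, 0 of 19 and 0 of 28 members past the threshold over all genes. With an estimated correlation the mitosis call held (adjusted p = 0.0227), while macrophage (adjusted p = 0.112) and cholesterol synthesis (adjusted p = 0.104) did not pass. Gpnmb was 105-fold above control by its group means (6.71 ± 0.76 log2, limma, adjusted p = 0.00307), with control at the floor. Mmp12 was 10.2-fold above control (3.35 ± 0.36). Cyp21a1, at 9.44 against 9.56 in control, differed by -0.11 (adjusted p = 0.723), and Cyp11b1 by 0.04 (0.927). The cholesterol exporter Abca1 fell 3.02-fold.

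Of 22 macrophage genes 1 rose, Gpnmb, against 11 adjusted over the list alone (median 0.41, adjusted p = 1.23e-10). Mitosis genes were higher by a median of 0.68 (adjusted p = 9.05e-28), with 0 of 28 past the threshold over all genes and 25 rising adjusted over the list alone. Top2a differed by 1.00 ± 0.20 (adjusted p = 0.0665) and Mki67 by 0.87 ± 0.20 (0.101). DNA replication had a median of 0.27, 0 of 27 past the threshold and 2 rising adjusted over the list alone (adjusted p = 1.73e-08; adjusted p = 0.062 with an estimated correlation). Cholesterol synthesis had a median of 0.57, 0 of 19 past the threshold and 13 rising adjusted over the list alone (adjusted p = 4.17e-12). Beside these groups the liver list had a median of 0.90 with 0 of 11 passing (adjusted p = 0.0058; adjusted p = 0.534 with an estimated correlation), which became 0.698 without day 3 replicate 1. The liver mean of control replicate 4 was 3.93, against 1.87 to 2.34 in the other controls. Interferon-stimulated genes had a median of -0.35 with 0 of 15 past the threshold and 3 falling adjusted over the list alone (adjusted p = 5.99e-06; adjusted p = 0.146 with an estimated correlation); the mean of day 3 replicate 4 lay above those of the other day 3 arrays. Immediate early genes had a median of 0.39, with 0 of 16 past the threshold and 2 rising adjusted over the list alone (adjusted p = 0.000114; adjusted p = 0.267 with an estimated correlation). Medulla genes had a median of 0.29 with 0 of 20 (adjusted p = 1.24e-06; adjusted p = 0.322 with an estimated correlation).

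Shifts with 0 members past the threshold were also seen for mast cell genes, near the floor in control (median 0.27, adjusted p = 0.0064; adjusted p = 0.231 with an estimated correlation) and Schwann and glial genes (0.16, 0.0463; adjusted p = 0.207 with an estimated correlation). Oxidative phosphorylation had a median of 0.07, about the size of the shift that median centring makes (0.0165; adjusted p = 0.228 with an estimated correlation), and kidney genes, with means of 1.21 and 1.08 at the floor in both groups, a median of -0.14 that cannot be read as a fall (0.0329; adjusted p = 0.193 with an estimated correlation). Zona fasciculata genes had a median of -0.09 (adjusted p = 0.16), steroid synthesis genes of -0.05 (0.655) and zona glomerulosa genes of -0.18 (0.269). Among single genes Mrap differed by -0.44 ± 0.12 (adjusted p = 0.181), Nr0b1 by 0.55 (0.216), Axin2 by 0.47 (0.272), Cyp11b2 by 0.35 (0.444), Star by -0.11 (0.676), Cyp11a1 by -0.12 (0.658), Nr5a1 by -0.07 (0.88), Mc2r by 0.13 (0.71) and Hsd3b1 by -0.03 (0.954). Shh differed by -0.16 (0.741), Gli1 by -0.27 (0.768), Ptch1 by -0.26 (0.703), Wnt4 by 0.04 (0.957), Rspo3 by -0.12 (0.9), Fkbp5 by -0.02 (0.982) and Th by 0.14 (0.905).

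Limma called 19 genes higher and 9 lower at day 3 than in control, 10 and 2 of them at least 2-fold, and over all 21439 genes the groups did not overlap for 1114 (2.86% by chance with 4 against 4). The other named rises were Atp6v0d2 (4.61 ± 0.75, a lower limit) and the acute phase protein Serpina3n (1.93 ± 0.31), and the falls were Abca1 (-1.59 ± 0.19), Adgrg2 (-1.27 ± 0.21), Nrbp2 (-0.84 ± 0.12) and Sbsn (-0.77 ± 0.12). Per-array median centring gave 18 higher and 35 lower, and a further quantile normalization 12 and 11. Without 1 array, 4 genes were higher when control replicate 4, day 3 replicate 2 or day 3 replicate 4 was left out, 5 without control replicate 3 and 8 without control replicate 1, and up to 15 otherwise. The number lower was 2 without control replicate 1, control replicate 4 or day 3 replicate 4, 3 without day 3 replicate 2, 4 without day 3 replicate 1, 5 without control replicate 3, and up to 13 otherwise. Gpnmb, Mmp12 and Abca1 passed in each of these 8 fits. The highest adjusted p of Atp6v0d2 and Serpina3n was 0.122 without day 3 replicate 4, that of Adgrg2 0.112 and of Sbsn 0.1 without day 3 replicate 2, and that of Nrbp2 0.0962 without control replicate 4. Sbsn passed in 0 of the 8 fits, Atp6v0d2, Serpina3n and Adgrg2 in 2 each and Nrbp2 in 4. The lists that lost their call were mast cell (0.12) without day 3 replicate 1, Schwann and glial cell (0.134) without day 3 replicate 3, and kidney (0.21) and oxidative phosphorylation (0.104) without control replicate 2. Of the 8 fits, Schwann and glial cell was lost in 4, kidney in 3, and oxidative phosphorylation and liver in 2 each. With the filter on dim probe sets the adjusted p was 0.0548 for oxidative phosphorylation, 0.0781 for Schwann and glial cell and 0.0911 for liver. With a further quantile normalization it was 0.0709 for Schwann and glial cell and 0.154 for kidney.

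At day 7, 4 genes still differed from control. Gpnmb was 38.8-fold higher by its group means (5.28 ± 0.76 log2, limma, adjusted p = 0.0362). Its levels were 7.19, 3.78, 8.99 and 7.45 in the 4 day 7 arrays against 1.02 to 2.03 in control, at the floor. The difference was 4.57 log2 without day 7 replicate 3 and 6.30 without day 7 replicate 2. Mmp12 was 5.90-fold higher (2.56 ± 0.36), Tmem71 (probe set 17317622) rose by 0.73 ± 0.11, and Mrap was lower by -0.81 ± 0.12, at 8.32 ± 0.16 against 9.13 ± 0.14, each at the same adjusted p of 0.0362.

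Of 10 steroid synthesis genes 0 passed, and 2 rose adjusted over the list alone, Cyp11b2 (0.49 ± 0.15; adjusted p over all genes 0.681) and Hsd3b6 (0.94 ± 0.30; 0.708), the latter named after its values were seen. The list did not pass (0.615). Cyp21a1 differed by -0.08 (adjusted p = 0.941), Star by 0.00 (1), Cyp11b1 by -0.06 (0.969), Cyp11a1 by -0.07 (0.949), Hsd3b1 by -0.06 (0.972) and Mc2r by 0.02 (0.993). Macrophage genes were higher as a group by a median of 0.26, 1 of 22 rising (6 adjusted over the list alone; adjusted p = 2.67e-09, and adjusted p = 0.135 with an estimated correlation). Immediate early genes had a median of 0.51 with 0 of 16 past the threshold and 2 rising adjusted over the list alone (adjusted p = 6.77e-09; adjusted p = 0.111 with an estimated correlation). For zona glomerulosa the median was 0.20, with 0 of 12 past the threshold and 2 rising adjusted over the list alone (adjusted p = 0.00691; adjusted p = 0.134 with an estimated correlation). Zona fasciculata genes had a median of -0.06 with Mrap the 1 of 9 that fell by either adjustment (adjusted p = 0.0284; adjusted p = 0.143 with an estimated correlation), and the ACTH list did not pass (0.966), with 1 of 10 falling, Mrap, against 3 rising and 2 falling adjusted over the list alone. Of the remaining lists with 0 members past the threshold, extracellular matrix had a median of -0.07 (adjusted p = 0.0224; adjusted p = 0.445 with an estimated correlation) and glucocorticoid receptor targets 0.10 (0.0318; adjusted p = 0.207 with an estimated correlation). MHC class II presentation had a median of 0.20 (0.0284; adjusted p = 0.331 with an estimated correlation) and T cell, near the floor in control, 0.17 (0.0354; adjusted p = 0.282 with an estimated correlation). Of other tissues, adipocyte genes had a median of -0.30 (0.0215; adjusted p = 0.465 with an estimated correlation) and liver genes of 0.62 (0.0188; adjusted p = 0.625 with an estimated correlation). The kidney list also passed, with a median of -0.14 (0.00691; adjusted p = 0.112 with an estimated correlation), but its means of 1.21 and 1.08 lie at the floor in both groups and cannot be read as a fall.

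The adjusted p was 0.986 for Mki67, 0.963 for Top2a, 0.924 for Nr0b1 and Axin2, 0.939 for Nr5a1, 0.955 for Shh, 0.965 for Gli1, 0.944 for Ptch1, 0.875 for Wnt4, 0.995 for Rspo3, 0.998 for Fkbp5 and 1 for Th. Limma called 3 genes higher and 1 lower, and over all 21439 genes the groups did not overlap for 676 (2.86% by chance). Each of the 4 lost its call in at least 6 of the 8 fits without 1 array, with adjusted p up to 0.192 for Gpnmb, Mmp12 and Tmem71 and 0.216 for Mrap without control replicate 4. Without control replicate 3, control replicate 4, day 7 replicate 3 or day 7 replicate 4, 0 genes were higher, and without control replicate 1 there was 1. The lower count was 5 without control replicate 2, and 0 without control replicates 1 or 4 or day 7 replicates 2, 3 or 4. With eBayes trend and robust options Gpnmb had an adjusted p of 0.22 and Tmem71 of 0.0631, and with array weights Gpnmb had 0.0529. The number of lists fell from 11 to 7 without control replicate 1, control replicate 2 or day 7 replicate 1, and macrophage and immediate early genes were the 2 lists that passed in each of the 8 fits. The highest adjusted p was 0.344 for MHC class II presentation, 0.547 for T cell and 0.19 for extracellular matrix without day 7 replicate 1, 0.0859 for zona fasciculata and 0.0845 for zona glomerulosa without day 7 replicate 2. It was 0.217 for glucocorticoid receptor targets without day 7 replicate 3, 0.285 for adipocyte without day 7 replicate 4, and 0.135 for kidney and 0.211 for liver without control replicate 2. With the filter on dim probe sets it was 0.107 for glucocorticoid receptor targets and 0.0775 for MHC class II presentation.

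Between day 3 and day 7, mitosis and cholesterol synthesis genes came down as groups (adjusted p = 0.0227 and adjusted p = 0.0502 with an estimated correlation, which the latter misses). Mitosis genes had a median of -0.60 (camera, adjusted p = 9.05e-28), all 28 with lower means, 0 past the threshold over all genes and 21 falling adjusted over the list alone. Mki67 differed by -0.81 ± 0.20 (adjusted p = 0.354) and Top2a by -0.86 ± 0.20 (0.31). Cholesterol synthesis genes had a median of -0.50, all 19 with lower means, 0 past the threshold and 16 falling adjusted over the list alone (adjusted p = 3.94e-17).

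DNA replication had a median of -0.25, 0 of 27 past the threshold and 9 falling adjusted over the list alone (adjusted p = 3.86e-12). Zona glomerulosa genes were higher by a median of 0.24 with 0 of 12 past the threshold and 3 rising adjusted over the list alone (adjusted p = 0.000101). For interferon-stimulated genes the median was 0.33, with 0 of 15 and 5 (adjusted p = 1.16e-06; adjusted p = 0.124 with an estimated correlation). Medulla genes had a median of -0.20 with 0 of 20 by either adjustment (2.03e-06; adjusted p = 0.329 with an estimated correlation), macrophage genes -0.13 with 0 of 22 (0.0474; adjusted p = 0.647 with an estimated correlation) and MHC class II genes 0.18 with 0 of 9 (0.0447; adjusted p = 0.38 with an estimated correlation). Neutrophil genes, at the floor at day 7 with a mean of 1.48, had a median of -0.28 with 0 of 12 (0.0451; adjusted p = 0.488 with an estimated correlation) and adipocyte genes -0.31 with 0 of 11 (0.0213; adjusted p = 0.465 with an estimated correlation). Without day 3 replicate 2 the adjusted p was 0.636 for macrophage and 0.625 for neutrophil, without day 3 replicate 3 it was 0.483 for adipocyte, and without day 7 replicate 1 it was 0.373 for MHC class II presentation. Of the 8 fits without 1 array, macrophage was lost in 5, and neutrophil, adipocyte and MHC class II presentation in 3 each. With the filter on dim probe sets it was 0.0531 for macrophage, 0.191 for MHC class II presentation and 0.0627 for adipocyte. Among the genes followed throughout, Mrap differed by -0.37 (0.493), Nr0b1 by -0.35 (0.7), Axin2 by -0.28 (0.752), Ptch1 by 0.43 (0.661), Shh by 0.27 (0.707), Wnt4 by 0.21 (0.804), Nr5a1 by 0.18 (0.77) and Cyp11b2 by 0.14 (0.879). The adjusted p was 0.964 for Cyp21a1, 0.865 for Cyp11b1, 0.8 for Star, 0.921 for Cyp11a1, 0.977 for Hsd3b1, 0.843 for Mc2r, 0.943 for Gli1, 0.914 for Rspo3, 1 for Fkbp5 and 0.936 for Th. Limma called 0 genes higher and 0 lower, with a smallest adjusted p of 0.0764, and 1516 genes had an unadjusted p under 0.05 against 1072 expected by chance. The lists that passed in none of the 6 contrasts were cholesterol uptake (smallest adjusted p 0.329), unfolded protein response (0.0828), B cell (0.208), smooth muscle and pericyte (0.0583) and pancreas (0.269). With array weights 2 genes were lower, without day 3 replicate 1 there were 7 lower, and in the other fits without 1 array up to 1 was higher and up to 1 lower.

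How far the genes changed at withdrawal went back was counted from these contrasts. Of the 921 genes called at withdrawal against control, 300 were called in the opposite direction at day 3 against withdrawal and 349 at day 7 against withdrawal, and 908 and 919 had the opposite point sign. Independent lists of these sizes would share 10.02 and 8.62 genes, but both contrasts use the same withdrawal arrays, which favours opposite signs. With the withdrawal arrays split in 6 ways, chosen after the results were seen, so that 1 or 2 of them select the genes and the others are compared with recovery, 243 to 750 genes were selected. Of these, 82% to 93.9% had the opposite point sign at day 3 and 88.4% to 96.3% at day 7, and 45 to 81 and 39 to 94 were called in the opposite direction. In the same direction, 17 of the 28 genes called at day 3 against control and 4 of the 4 at day 7 against control were among the 921, where independent lists would share 0.64 and 0.09. In 20 simulations with no effect the mean was 0, as few genes are called there, which makes it no measure of the overlap without change. The 4 are Gpnmb, Mmp12, Mrap and Tmem71, which differed by 7.63, 3.79, -1.79 and 1.37 log2 at withdrawal. With the controls split, controls 1 and 2 against withdrawal called 342 genes, of which 7 were called at day 3 and 0 at day 7 against the other controls, where 25 and 2 genes were called in all. Their median change toward the call was 0.81 log2 at withdrawal, with 0.19 left at day 3 and 0.12 at day 7. Controls 3 and 4 called 463 genes, and against the other controls 0 and 0 genes were called in all, so that only the sizes can be compared. Here the median change was 0.73, with 0.20 and 0.14 left. In both splits the change at withdrawal uses the withdrawal arrays that selected the genes, which can make it too large. The recovery arrays were not part of the selecting contrast, so the part that went back can be overstated. The number that moved back by day 7 was 170 without withdrawal replicate 2, 225 without withdrawal replicate 1, and 214, 225 and 223 without day 7 replicates 1, 2 and 4. The number still different was 8 without control replicate 2, 5 without day 3 replicate 2, 3 without day 7 replicate 2, 2 without day 7 replicate 1, 1 without control replicates 1 or 3, and 0 in the other fits without 1 array.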

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

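Single arrays that stood apart from their group were looked for in each group of 4 with Dixon's ratio, the gap to the nearest array over the range of the group, at its critical value for groups of 4. Chance picks out about 1 in 20 groups. Among 96 groups of list means 6 passed where 4.8 are expected, and among 288 groups of named genes 23 passed where 14.4 are expected; of 3 groups of array medians 0 passed. The tests of the patterns below were chosen only after the results were seen, and the splits of the samples were fixed before.

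For list means, day 3 replicate 2 was high for mitosis (ratio 0.939; 4.35 against 4.04 to 4.06) and neutrophil (0.854), replicate 4 was high for interferon-stimulated genes (0.93) and replicate 1 was low for T cell (0.968). At day 7, replicate 2 was low for B cell (0.899) and replicate 4 was low for adipocyte (0.878).

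For named genes, control replicate 2 was low for Vnn3 (0.935; 2.74 against 4.68 to 4.82), Tacr2 (0.86), Cryba4 (0.902), Mrap (0.877), Sqle (0.86) and Tcf21 (0.919), and high for Aldh1a7 (0.954) and Wfdc17 (0.874). Control replicate 1 was low for Abcb1b (0.922) and Atf3 (0.877), replicate 3 was high for Gabrg3 (0.885) and replicate 4 was low for Erg (0.856). At day 3, replicate 4 was low for Cd4 (0.846) and Pik3c2g (0.904), replicate 2 was low for Gli1 (0.943) and replicate 1 was low for H1f5 (0.839). The day 3 levels of Cd4, Pik3c2g and Gli1 lie at the floor. At day 7, replicate 3 was high for Lgr5 (0.842), Ddc (0.89) and Wfdc17 (0.875), replicate 2 was low for Klf4 (0.891) and Top2a (0.841), replicate 1 was high for Tmem144 (0.84) and replicate 4 was low for Erg (ratio 1, by less than 0.02 log2). Control replicate 2 holds 8 of the 12 control entries. Over the 774 genes called between withdrawal and control without it, this array lay 0.16 log2 toward withdrawal by the median, and 551 of them lay that way; for controls 1, 3 and 4 the medians were 0.017, 0.062 and 0.08. The cause was not tested.

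Lists that differed between day 7 and day 3 were picked out because the test compares 2 time points of the same recovery. The median differences were -0.496 for cholesterol synthesis, 0.238 for zona glomerulosa, -0.248 for DNA replication, -0.601 for mitosis, 0.333 for interferon-stimulated genes, -0.199 for medulla, -0.128 for macrophage, 0.177 for MHC class II presentation, -0.278 for neutrophil and -0.305 for adipocyte genes. With an estimated correlation 3 of the 10 held: zona glomerulosa, DNA replication and mitosis.

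Outside the genes analysed, 10337 probe sets carry no single gene symbol. At withdrawal 45 of them were higher than in control and 37 lower, in a test over all probe sets. What they measure was not tested.

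The first pattern weighed is the rise of macrophage genes at withdrawal. If a smaller cortex raised all other cell types alike, macrophage genes would rise as medulla genes do, and they rose 0.41 ± 0.124 log2 more. Their shift of 0.874 log2 was 0.762 ± 0.111 with per-array median centring and 0.846 ± 0.12 with a further quantile normalization, which argues against an offset or a difference in distribution left between arrays as the whole cause; what the deposited normalization itself did was not tested. From withdrawal to day 7 they fell by 0.542 ± 0.117, while about 2 weeks of age would not run back. The medulla and day 7 values argue against a smaller cortex and against age as the whole cause, while for genes still different at day 7, age and treatment are not separated by this design.

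The second pattern is the rise of cholesterol synthesis and mitosis genes from control to day 3, in arrays with unequal levels of liver genes (5.44 in day 3 replicate 1, 3.77 in replicate 3 and 3.93 in control replicate 4) and with neutrophil genes highest in day 3 replicate 2. The cholesterol synthesis shift of 0.49 log2 was 0.489 ± 0.159 with the liver mean of each array as covariate and 0.352 ± 0.121 with the neutrophil mean. The mitosis shift of 0.647 was 0.681 ± 0.147 and 0.578 ± 0.145. Taken 1 at a time, neither mean accounts for all of either rise, though part of the cholesterol synthesis shift goes with the neutrophil mean. The 2 means, high in different day 3 arrays, were entered together only in the covariate fit, whose shifts are not given here. Cholesterol synthesis averaged 6.625 and 6.741 in day 3 replicates 1 and 2, 6.257 and 6.263 in replicates 3 and 4, and 5.652 to 6.105 in control. Mitosis averaged 4.038, 4.346, 4.052 and 4.057 in day 3 replicates 1 to 4, and 3.244 to 3.692 in control.

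The third pattern is that medulla, capsule, Schwann and zona glomerulosa genes were all higher at withdrawal as groups, with 3 of 20, 1 of 12, 0 of 9 and 5 of 12 members past the threshold. With an estimated correlation only zona glomerulosa held (adjusted p = 0.0494), against 0.252 for medulla, 0.108 for capsule and 0.062 for Schwann. A smaller share of zona fasciculata would raise the 4 lists alike, and zona glomerulosa minus capsule was 0.179 ± 0.131, which leaves that explanation open. Endothelium minus medulla was -0.773 ± 0.179, which decides nothing here, as the part of endothelium inside the zona fasciculata was not measured. No cell counts or gland weights were used here, so that the share of each layer was not measured.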

How the results depend on the processing

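Each result was computed again under the alternatives named above; the fits without day 3 replicates 1 and 2 and with liver and neutrophil covariates and the split of the withdrawal arrays were chosen after seeing the data. Of 2565 values for named differences that passed, 2056 kept their side of the threshold, 509 did not and 0 changed sign. Of 1232 values for list calls, 1000 kept their side, 227 did not and 5 changed sign; 2 more changed sign among lists that had not passed. Where nothing else is said, the cause was not tested. Counts are given as higher and lower.

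The filter on dim probe sets, which tests fewer genes, gave 329 and 306 for day 7 against withdrawal, 48 and 28 for day 3 against control, 7 lists for day 7 against control and 527 genes moved back; 17 list calls and 0 named genes were lost. Median centring gave 341 and 853 for withdrawal against control, 391 higher for day 7 against withdrawal and 35 lower for day 3 against control, and 6 named genes were lost. A further quantile normalization gave 12 higher for day 3 against control. With trend and robust options there were 52 and 39 for day 3 against control and 1 higher for day 7 against control. Array weights gave 14 lower for day 3 against control and 2 lower for day 7 against day 3. All probe sets of the table, with more tests, gave 6 and 4 for day 3 against control and 4 lower for day 7 against control. With the probe set of largest variance, Cyp11a1 did not pass for withdrawal against control (0.532), day 3 (0.759) or day 7 (0.382) against withdrawal, and Cox5b had 0.222 for day 3 against withdrawal.

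A size of at least 1 log2 unit left 151 and 78 for withdrawal against control, 78 and 43 for day 3 and 53 and 46 for day 7 against withdrawal, 10 and 2 for day 3 against control and 0 lower for day 7 against control. Models of only the 2 groups, with fewer arrays to estimate the spread, gave 311 and 213 for withdrawal against control, 109 and 52 for day 3 and 94 and 60 for day 7 against withdrawal, 8 and 1 for day 3 against control and 0 and 0 for day 7 against control; 60 named genes were lost. Camera with an estimated correlation left 5, 9, 5, 1, 0 and 3 lists in the order of processing. Fry passed 11 for day 7 against withdrawal, 6 for day 3 and 1 for day 7 against control and 5 for day 7 against day 3. With split controls 0 and 0 genes were still different at day 7, but only 2 and 0 genes were called there in all, so that these counts do not show whether genes still differed. With the withdrawal arrays split, 88, 89, 94, 59, 83 and 39 genes moved back by day 7 when arrays 1, 2, 3, 1 and 2, 1 and 3, and 2 and 3 selected them, with 1 or 2 withdrawal arrays left per fit and a lone array taken to vary like the other groups.

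With the replicate number as a block there were 300 and 244 genes for withdrawal against control, 166 and 91 for day 3 and 133 and 88 for day 7 against withdrawal, 3 and 1 for day 3 against control, 0 and 0 for day 7 against control, 0 still different and 196 moved back. The residuals showed no pairing by number: over 21 pairs with the same number their correlation ran from -0.138 to 0.06 and 0 were over 0.1. Of 15 arrays 0 correlated best with its own number. A pairing too weak to show in the residuals is not excluded. With the block 50 named genes and 3 list calls were lost. The block also costs degrees of freedom.

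Without day 3 replicates 1 and 2 there were 145 and 60 genes for day 3 against withdrawal, 3 lower for day 3 against control, 0 and 2 for day 7 against control, 1 and 6 for day 7 against day 3, and 2 still different. Between day 7 and day 3 the immediate early (adjusted p = 0.0302) and neutrophil (0.943) lists changed sign. The covariates gave 102 and 35 for day 3 and 123 and 74 for day 7 against withdrawal, 7 and 2 for day 3 against control, 0 and 0 for day 7 against control, 2 lower for day 7 against day 3, 0 still different and 181 moved back. Liver genes changed sign for day 7 against withdrawal (0.885), day 3 against control (0.943) and day 7 against control (0.647), and neutrophil genes for day 7 against day 3 (0.885), by construction, since each is its own covariate.

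Without 1 array at a time the counts ran, from lowest to highest, from 243 to 469 higher and 216 to 354 lower for withdrawal against control, 130 to 227 and 79 to 165 for day 3 against withdrawal, and 125 to 189 and 75 to 226 for day 7 against withdrawal. They ran from 4 to 15 and 2 to 13 for day 3 against control, 0 to 4 and 0 to 5 for day 7 against control, and 0 to 1 and 0 to 7 for day 7 against day 3. Lists for day 7 against control ran from 7 to 13, genes moved back from 170 to 363 and genes still different from 0 to 8. The liver list for day 7 against day 3, which did not pass, had adjusted p from 0.0288 to 0.84 and changed sign without day 3 replicate 1 (0.0338). Fewer arrays lower the counts by themselves. Signal over background limits genes near the floor, such as Akr1c18, Pik3c2g and Gli1, for which a fall cannot be seen.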

Other observations

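Of the 17 genes that were called in the same direction at withdrawal and at day 3 against control, Gpnmb is the 1 member of the fixed macrophage list. Among the others, the galectin Lgals3 lay at the floor in control and differed from it by 2.15 log2 at withdrawal and 1.23 at day 3. Ms4a7 differed by 1.80 and 1.06, and Ptafr, the receptor of platelet-activating factor, by 1.96 and 1.08. Tmem71 differed by 1.37 and 0.81, Spock3 by 1.28 and 0.98 and Serpina3n by 1.58 and 1.93. Those that stayed lower include Gramd1b, a cholesterol transfer protein, by -1.54 and -0.66, Alas1, which starts haem synthesis, by -0.61 and -0.65, and Sbsn by -1.60 and -0.77. The day 3 call of Sbsn against control was lost in each fit without 1 array. Apart from Gpnmb, Serpina3n, Sbsn and Tmem71, these genes were chosen after their values were seen.

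Other splits of the arrays show how often a grouping other than the labels gives as many calls; they were planned before the results were seen. For withdrawal against control 1 of 35 splits, the real one, reached 921 genes, and the next called 80, with controls 1, 3 and 4 against the rest. For day 3 against withdrawal it was 1 (483 genes, next 8), for day 7 against withdrawal 1 (404, next 70), for day 3 against control 1 (28, next 1) and for day 7 against control 1 (4, next 2). Between day 7 and day 3 all 35 splits had as many as the 0 genes called, and the highest called 1. For list calls the real split was the highest for withdrawal against control (1 of 35; 19 lists, next 16) and day 7 against control (1; 11, next 10). Counting the real split, as many lists shifted in 3 splits for day 3 against withdrawal (17, highest other 21). For day 7 against withdrawal it was 2 (17 and 17) and for day 3 against control 2 (12 and 12). For day 7 against day 3 it was 11 (10 and 13). So many list calls between these groups thus also arise with other groupings.

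Of 100 splits of control, withdrawal and day 7 arrays, all but the real split were drawn. Counting it, 2 had at least its 4 genes still different (highest 90), and 2 its 349 moved back (highest 374). The draws with the highest values keep the 3 withdrawal arrays together, under their own name or with day 7 replicate 3 under the name of control, so that these numbers reflect the distance of the withdrawal arrays from the rest.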
